A study of Danio rerio with 2 samples.

How the data were processed

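Gene expression was measured in single cells of pooled zebrafish embryos at 120 hpf, with 1 library of wild-type control embryos and 1 of embryos exposed to polystyrene nanoparticles of 20 nm. Per the labels' protocols, dead cells were removed on columns, a recovery of 10000 cells was aimed for, and libraries were made with a 5 prime chemistry of 10x Genomics. The deposited values are UMI counts per gene and cell, not normalized. Per the submitters' processing notes, reads were checked with FastQC, counted with Cell Ranger 6.0.0 against the build GRCz11, and processed further with Seurat 4.3.0 under R 4.2.2. No Seurat step is visible in the counts. The lowest total per barcode was 500 UMIs in both libraries, so the matrices held called cells and no empty droplets, and free RNA could not be estimated from them. Gene symbols came from the same files as the counts, and IDs that shared a symbol were summed. Cell labels of the submitters were not analysed here; all cell names were rebuilt.

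Cells were kept with at least 200 detected genes and at most 20% of UMIs from mitochondrially encoded genes. Under 200 genes were 174 control and 84 exposed cells, and 1105 and 897 were over the mitochondrial limit. Doublets were called with Scrublet as included in scanpy 1.11.5; it marked 1 control and 0 exposed cells, which is too few for droplet libraries of this size, so doublet calling has not worked here and doublets remain among the kept cells. An alternative that removed the top 8% of doublet scores was added after the data were seen. Both libraries were clustered together without batch correction, on 2000 variable genes after log normalization, with globin and mitochondrially encoded genes left out, 30 principal components, 15 neighbours and the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). A cluster took the name of a class, written as class-like, only where its leading genes met a marker rule fixed before the data were examined; other clusters stayed unnamed. The leukocyte-rich cluster was split once more after the data were seen. Genes that define a cluster are not results about exposure.

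Class shares are percentages of kept cells with exact Clopper-Pearson 95% intervals, and ratios of shares or of UMIs have exact conditional 95% intervals; both cover counting error only. For gene ratios, UMIs were summed over the cells of a class and divided by the sum without globin and mitochondrially encoded genes; globins and mitochondrially encoded genes were divided by all UMIs. Genes needed at least 50 UMIs over both libraries, and classes at least 100 cells in each. Medians of 37 gene lists fixed beforehand were set beside 10000 random lists drawn from 20 bins of expression. Percentiles describe these libraries and are not tests. Counting intervals of lists were seen to be too narrow where few cells carry most UMIs, so intervals from 2000 redraws of the cells of each library were added; they cover the sampling of cells, not of fish. A cell counted as cycling with at least 1 UMI of a cycling gene after thinning to 500 UMIs.

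Named genes followed a rule fixed beforehand: the 10 highest and 10 lowest ratios in erythroid-like cells and in all kept cells, and 3 and 3 in each other class, ranked by the interval bound nearer to 1. Within a class, the gene's level also had to be at least that over all kept cells, against free RNA. Globins, mitochondrially encoded genes and loci without a gene name were ranked but only counted. Up to 4 members per list, those with the most UMIs, were named too, and in erythroid-like cells all measured members of the globin, heme synthesis and transcription factor lists, except 1 heme synthesis member that is not reported here. Names outside the rule are cluster 31 and sub-cluster genes and the genes near absent from 1 library, chosen after their values were seen.

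Steps were tested on simulated counts with known ratios. For erythroid-like cells, with 5322 genes, intervals lay on the right side of 1 for 92.0% of genes at a ratio of 2.00, 68.0% at 1.50, 58.1% at 0.667 and 75.6% at 0.500, and off 1 for 3.76% of unchanged genes. For all kept cells, with 17424 genes, these shares were 98.0%, 88.0%, 87.8%, 96.0% and 4.42%. The simulation drew independent counts, so it did not cover UMIs that gather in few cells.

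Alternatives covered cell filters, clustering resolution, the genes used for clustering, classes from marker scores, each library clustered alone, other denominators and scalings, minimum UMIs and thinning. Explanations were tested for the cluster 31 share, the S phase list, the S phase level in cells with over 30% globin, the genes near absent from 1 library and the heme synthesis list, and the last was followed through cells of different globin share. Some rules changed after first results. Intervals from redrawn cells replaced counting intervals in the S phase tests, which turned 4 verdicts against technical explanations into open ones. For the heme list, the bound written beforehand was met by its value but within its spread, and the first verdict against the explanation was likewise made open. A verdict on genes near absent from 1 library was corrected to open because its written bound had been misread. Cluster 31 was picked for its low share among 41 clusters, so the intervals behind its verdicts were widened for that choice (the error of 95% intervals divided by the number of clusters). This turned 2 verdicts on odds ratios, whose 95% intervals lay under 1, from against the explanation to open. The verdict on doublets was made open as well, since doublet calling had not worked. Genes ranked in epidermis-like and fibroblast or mesenchyme-like cells were afterwards measured in each cluster of the class alone, and genes near absent from 1 library were set beside their share of cells outside the cluster. Computing used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. With 1 library per group, no p-values and no counts of changed genes were computed.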

Results

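Single cells from pooled zebrafish embryos at 120 hpf were profiled in 2 libraries, 1 from wild-type control embryos and 1 from embryos exposed to polystyrene nanoparticles of 20 nm. The series asks how the particles act on erythropoiesis, the making of red blood cells. The control library held 12204 cell barcodes with 55697259 UMIs, and the exposed library 11769 barcodes with 62505219 UMIs. After filters, 11094 control and 10870 exposed cells remained, with median depths of 2858 and 3213 UMIs per cell. Each group had 1 library, so no test between groups was possible and no difference could be held against the spread between pools of fish. Intervals are exact 95% intervals that cover counting error only, unless they are said to come from redrawn cells.

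Erythroid-like cells, marked by larval globins, alas2 and slc4a1a, made up 8.27% of control cells (917 cells, 95% interval 7.76 to 8.79) and 6.16% of exposed cells (670 cells, 5.72 to 6.63), a ratio of 0.746 (0.674 to 0.825). Epidermis-like cells, the largest named class of the exposed library, were at 17.0% and 24.4%, a ratio of 1.43 (1.35 to 1.52). Neuron-like cells had a ratio of 1.85 (1.42 to 2.42) and cartilage-like cells 1.17 (1.04 to 1.32). The neuron-like class joins cluster 25 at 1.59 (1.19 to 2.12) with the small cluster 37 (6 and 32 cells) at 5.44 (2.24 to 15.9). The cartilage-like class joins clusters that went opposite ways, cluster 8 at 0.905 (0.774 to 1.06) and cluster 17 at 1.77 (1.45 to 2.17). Lower shares in the exposed library were seen for fibroblast or mesenchyme-like cells at 0.835 (0.780 to 0.894), lens-like cells at 0.640 (0.472 to 0.863) and proliferating-like cells at 0.721 (0.565 to 0.918). Shares of 1 library sum to 100%, so a larger epidermis-like class lowers all others; among cells outside it, erythroid-like cells were at 9.96% and 8.15%, a ratio of 0.819 (0.740 to 0.905). Among blood cells alone, where erythroid-like cells were at 69.6% and 72.4%, the ratio was 1.04 (0.940 to 1.15), since leukocyte-rich cells were lower too. Clusters that no marker rule could name held 31.8% of control and 29.3% of exposed cells. The cartilage-like ratio turned to 0.959 with a minimum of 500 detected genes and to 0.726 with each library clustered alone, the proliferating ratio to 1.49 with each library clustered alone, and the fibroblast ratio to 1.26 at a finer resolution.

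**Figure D1:**
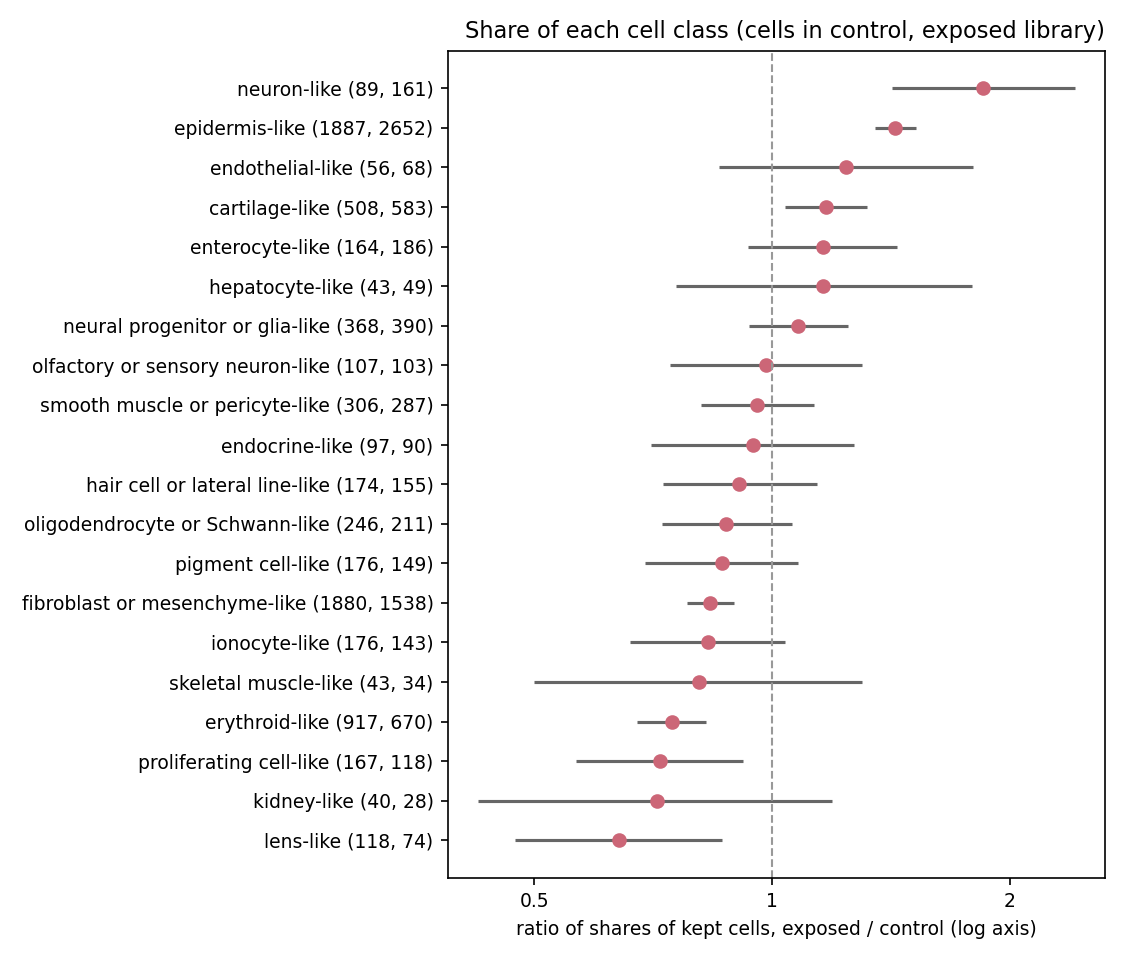
Ratio of each named cell class's share of kept cells, exposed over control, on a log axis with exact 95% counting intervals. Neuron-like (1.85) and epidermis-like (1.43) cells lie above 1, and erythroid-like (0.746) and lens-like (0.640) cells below it.

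Within the blood cells, shares were counted by cluster. The erythroid-like class joins clusters 4 and 31 with smaller clusters that together hold 47 control and 44 exposed cells. Cluster 4, the globin-rich red cells, had 788 control and 594 exposed cells, a ratio of shares of 0.769 (0.690 to 0.857). Cluster 31, erythroid-like cells led by the anion exchanger slc4a1a and the heme enzymes urod and hmbsb, had 82 and 32 cells (0.739% and 0.294% of kept cells), a ratio of 0.398 (0.256 to 0.606). With each library clustered alone, no ratio was taken for this cluster. Over the other settings tried, its ratio ranged from 0.360 to 0.531. The latter (0.414 to 0.678, 196 and 102 cells) came with globin and mitochondrially encoded genes among the clustering genes. Cluster 9, the leukocyte-rich cells, had 400 and 255 cells, a ratio of 0.651 (0.554 to 0.763). Inside cluster 9, a sub-cluster with spi2, meis1b, fli1a and myb, the last a regulator of blood stem and progenitor cells, had 97 and 42 cells, and a proliferating sub-cluster had 69 and 22. Together these were 1.5% and 0.589% of kept cells, a ratio of 0.393 (0.290 to 0.528), while the other cells of cluster 9 were at 0.833 (0.684 to 1.01). The sub-clusters pooled here had the lowest ratios of those in cluster 9, at 0.442 and 0.325. A low pooled ratio and a higher ratio of the other cells therefore follow from pooling them, and the interval is not widened for it. The split of cluster 9, and the choice of cluster 31, were made after the clusters had been seen.

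**Figure D2:**
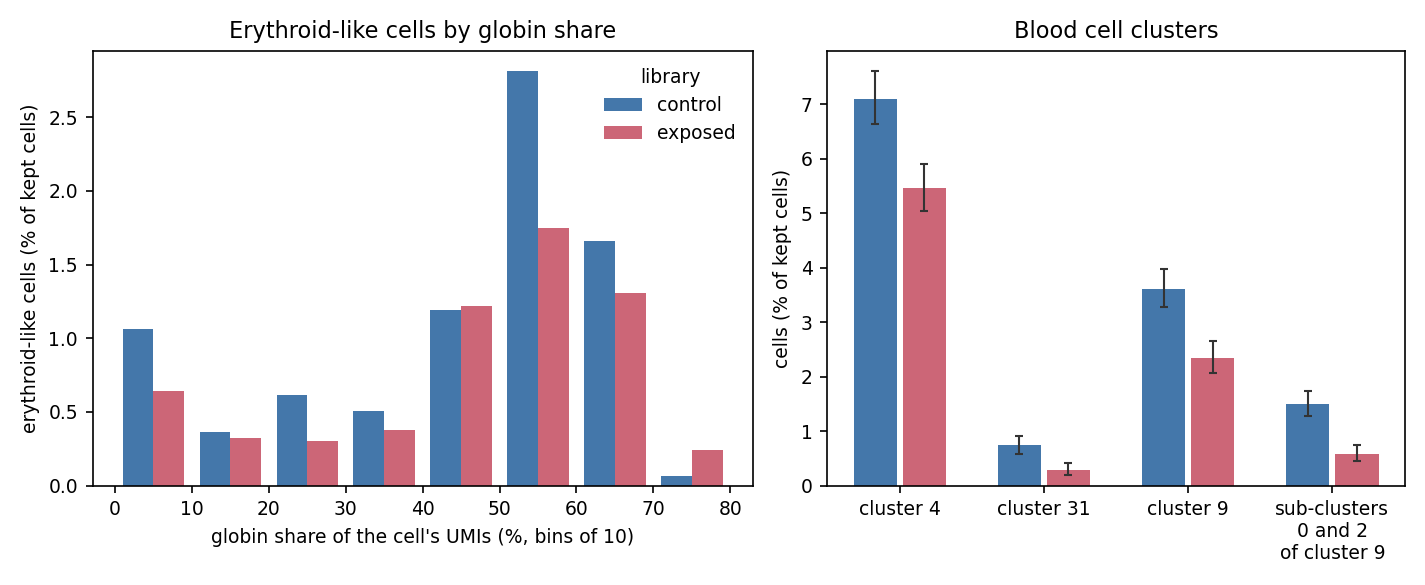
Left, erythroid-like cells of both libraries by the globin share of their UMIs (bars, % of kept cells); right, blood cell clusters as % of kept cells with exact 95% counting intervals. Cluster 31 was at 0.739% of control and 0.294% of exposed cells.

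Globin mRNA took 34.2% of all UMIs of erythroid-like cells in the control library and 41.1% in the exposed one, a ratio of 1.2. The 9 measured larval globins were all higher in the exposed library, with hbbe1.1 at 1.22 (1.21 to 1.22), hbae3 at 1.16 (1.16 to 1.17), hbbe2 at 1.22 (1.21 to 1.23), hbbe1.3 at 1.3 (1.29 to 1.32), hbbe1.2 at 1.1 (1.09 to 1.12), hbae1.3 at 1.16 (1.14 to 1.18), hbae1.1 at 1.21 (1.17 to 1.25), hbae5 at 1.60 (1.49 to 1.72) and hbbe3 at 1.31 (0.864 to 1.97). No adult globin was measured. The typical cell did not differ in this way, as the median globin share per cell was 51.6% in both libraries. Erythroid-like cells with under 30% globin, a limit chosen after the data were seen, were 24.6% of that class in the control library and 20.6% in the exposed one (ratio 0.836, 0.671 to 1.04), with median depths of 5284 and 2456 UMIs. Thinned to 500 UMIs per cell, the globin shares were 43.7% and 45.6%, and in cells picked by non-globin markers they were 8.59% and 7.14%, the opposite direction. Outside erythroid-like cells, globins took 0.171% of control and 0.239% of exposed UMIs, but the medians per cell were 0.0747% and 0.0748%. The larval globin list went both ways there, at -0.47 in epidermis-like, -0.87 in pigment cell-like and 2.2 in enterocyte-like cells.

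Genes of DNA replication were lower in erythroid-like cells of the exposed library. The median log2 ratio of the 36 measured S phase genes was -0.67, below all 10000 random lists matched for expression, as a description of these libraries, and 23 of them were lower by more than 1.5-fold. Examples are pcna, the sliding clamp of DNA polymerases (0.677, 0.607 to 0.754), dut, which removes dUTP (0.526, 0.439 to 0.628), rrm1, a subunit of ribonucleotide reductase (0.677, 0.553 to 0.825), and mcm4, part of the replicative helicase (0.741, 0.598 to 0.914). The 18 DNA damage repair genes had a median of -0.51, with the single-strand binding protein rpa2 at 0.534 and the histone variant h2ax at 0.717. The 45 G2 and M phase genes had a median of -0.21, with mki67 at 0.866, cdk1 at 0.736 and hmgb2a at 0.878. Cells with a cycling gene after thinning to 500 UMIs were 34.4% of control and 27.9% of exposed erythroid-like cells (ratio 0.813, 0.674 to 0.977), but neuron-like cells were at 48.3% and 56.5%, so this share is not read as a share of dividing cells. In skeletal muscle-like cells it was 3 of 43 and 1 of 34 cells, and without thinning the erythroid-like ratio was 0.997. Few cells carried the S phase UMIs, 50% of them lying in 40 control and 13 exposed cells, and redrawing the cells gave intervals of -1.08 to -0.32 for S phase, -0.98 to -0.23 for DNA repair and -0.82 to 0.30 for G2 and M phase. In cluster 31, with 32 exposed cells, the medians were -0.35 for S phase (26 members, -0.80 to 0.09 from redrawn cells) and 0.17 for G2 and M phase (44 members, -0.29 to 0.56). In cluster 4 the G2 and M phase median was -0.32 (-0.88 to 0.02 from redrawn cells) over 8 members. S phase genes also had a median of -0.54 over all kept cells, -0.42 in epidermis-like cells and -0.14 in fibroblast or mesenchyme-like cells.

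**Figure D3:**
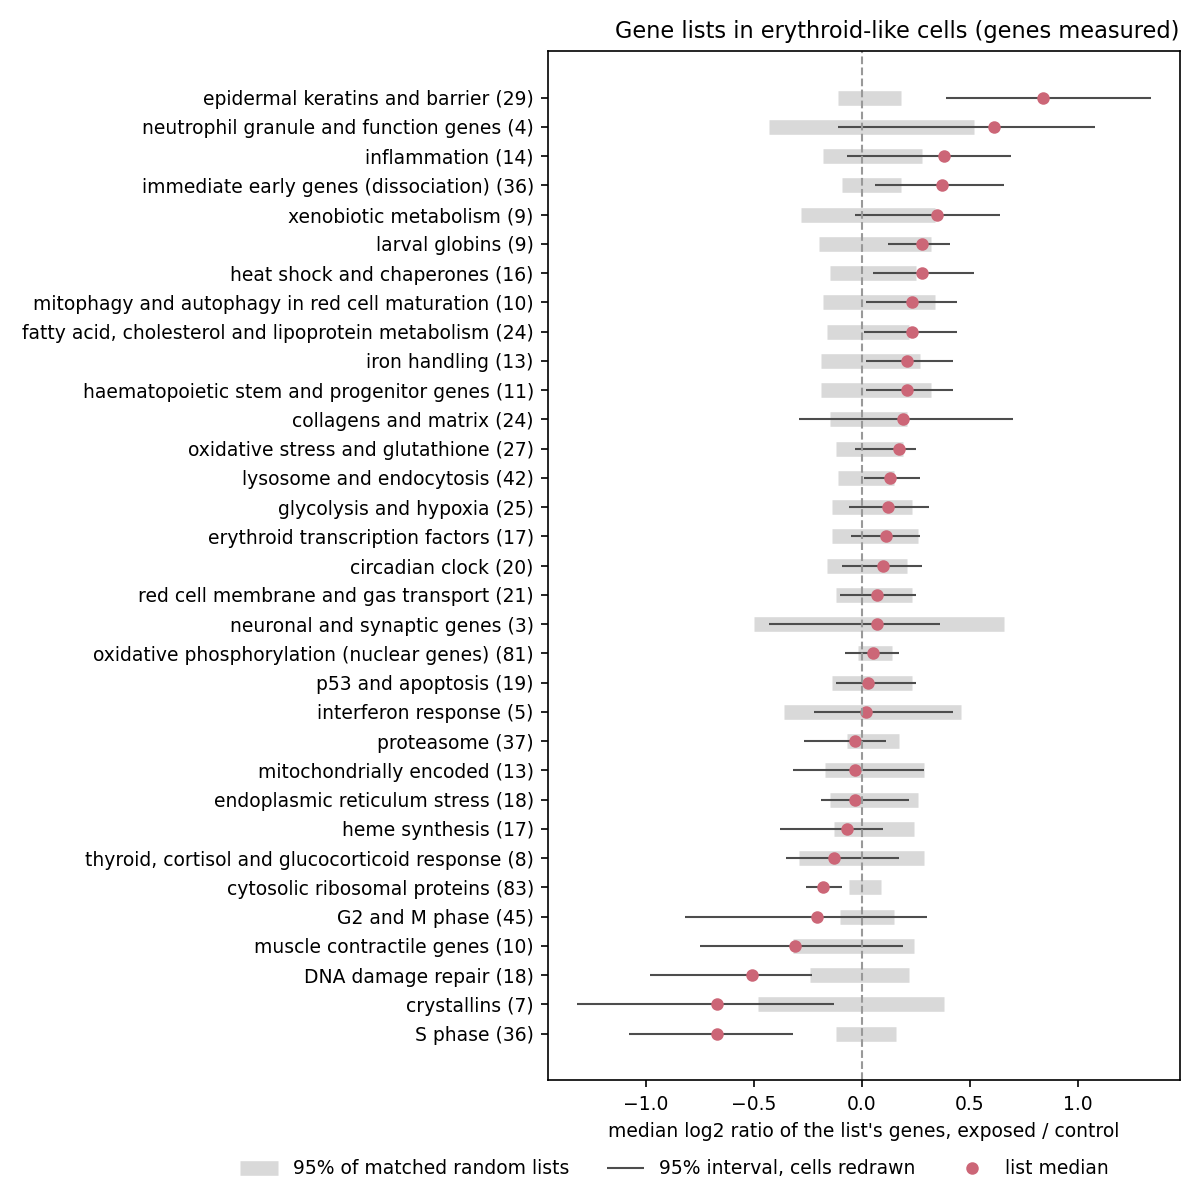
Median log2 ratio of each gene list in erythroid-like cells, exposed over control, with the 95% interval from redrawn cells (line) and the range of matched random lists (grey band). S phase genes and crystallins (both -0.67) lie lowest and epidermal keratins (0.84) highest. Crystallins are proteins of the lens, and their list was lower in epidermis-like cells too (-1.31). The heat shock, mitophagy, oxidative stress, membrane and transcription factor medians turn negative with each cell weighted equally.

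Heme synthesis genes had a median log2 ratio of -0.07 over 17 members in erythroid-like cells, at percentile 10.0 of matched random lists, with an interval from redrawn cells of -0.38 to 0.10. Of the enzymes, alas2, which starts erythroid heme synthesis, was at 0.977 (0.934 to 1.02) and alas1 at 1.2 (1.09 to 1.33). Of the other enzymes, those with an interval under 1 were hmbsb at 0.675 (0.590 to 0.771), hmbsa at 0.746 (0.648 to 0.858), urod at 0.766 (0.710 to 0.825), alad at 0.815 (0.685 to 0.966) and the ferrochelatase fech at 0.747 (0.569 to 0.974). Those with an interval including 1 were cpox at 0.864 (0.739 to 1.01), ppox at 0.952 (0.682 to 1.32) and uros at 0.999 (0.855 to 1.17). The transporters and partners were tspo at 1.1, tmem14ca at 1.03, slc25a37 at 1.0, slc25a39 at 0.997, slc25a38b at 0.984 and abcb10 at 0.855. The 17 erythroid transcription factors and their partners had a median of 0.11 (percentile 70.0), which turned to -0.05 with all UMIs as the denominator and to -0.04 with each cell weighted equally. Members with an interval including 1 were gata1a at 1.07 (0.923 to 1.23), klf1 at 1.09 (0.923 to 1.29), the erythropoietin receptor epor at 1.05 (0.893 to 1.24), nfe2 at 1.06, myb at 1.1, zfpm1 at 0.985, trim33 at 1.0, foxo3a at 0.926, foxo3b at 1.1 and bcl11aa at 1.28 (0.870 to 1.87). Those with an interval off 1 were tal1 at 0.772 (0.634 to 0.938), klf17 at 0.708 (0.545 to 0.916), lmo2 at 1.16 (1.06 to 1.27), gfi1b at 1.31 (1.1 to 1.55), klf6a at 1.39 (1.1 to 1.75), klf3 at 1.55 (1.04 to 2.32) and hemgn at 1.08 (1.03 to 1.13).

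**Figure D4:**
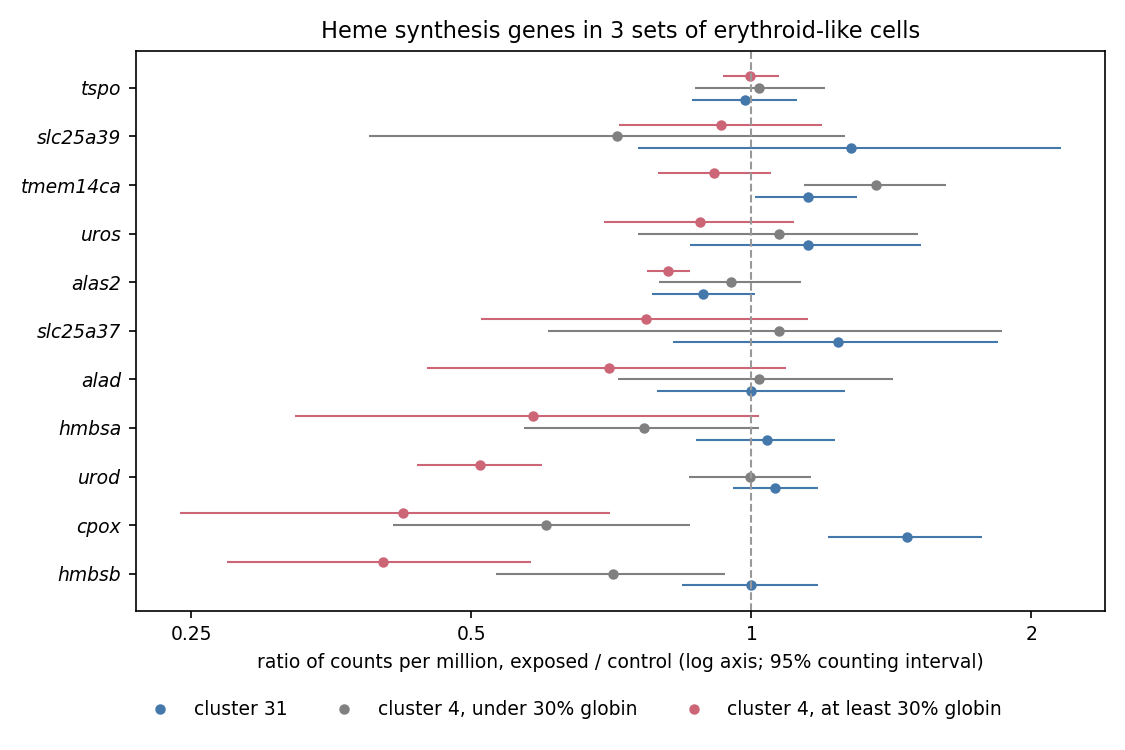
Ratios of heme synthesis genes with at least 60 UMIs in each of 3 sets, exposed over control, for these sets of erythroid-like cells, on a log axis with 95% counting intervals. In cluster 4 cells with at least 30% globin urod was at 0.511 and hmbsb at 0.402, while in cluster 31 they were at 1.06 and 1.0; the globin limit was chosen after the data were seen.

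Iron handling genes had a median of 0.21 over 13 members, with the ferritin chain fth1a at 1.27 and fthl27 at 1.38; it turned to -0.02 in cells thinned to 1000 UMIs. Red cell membrane and gas transport genes had a median of 0.07 over 21 members, with the carbonic anhydrase cahz at 1.22, slc4a1a at 0.721 and the ammonium transporter rhag at 0.884; it turned to -0.10 with all UMIs as the denominator, -0.05 with each cell weighted equally and -0.03 in thinned cells. With all UMIs as the denominator, the median of all genes moved from 0.02 to -0.14. Mitophagy and autophagy genes had a median of 0.23, with bnip3lb at 1.25, and turned to -0.03 with each cell weighted equally.

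Heat shock genes and chaperones had a median of 0.28 over 16 members in erythroid-like cells, with the inducible hsp70l at 1.5 (1.46 to 1.54), hspa8 at 1.05 and hsp90ab1 at 0.939. This median turned to -0.02 with each cell weighted equally, and was 0.32 in epidermis-like and 0.25 in fibroblast or mesenchyme-like cells. Immediate early genes, which dissociation of tissue also raises, had a median of 0.37 over 36 members, with cebpb at 1.48 and junbb at 1.18. Their median was 0.56 in cluster 4 and -0.27 in cluster 31 (-1.15 to 0.46 from redrawn cells). Outside erythroid-like cells it was 0.57 in the leukocyte-rich cluster 9, 0.13 in ionocyte-like and -0.08 in epidermis-like cells. Inflammation genes had a median of 0.38 over 14 members, with the prostaglandin synthase ptgs2a at 2.31 and the chemokine cxcl8a at 1.32, and an interval from redrawn cells of -0.07 to 0.69. In cluster 4 alone the inflammation median was 0.10 over 12 members (-0.25 to 0.44 from redrawn cells), with cxcl8a at 0.922 (0.757 to 1.12). Cytosolic ribosomal proteins had a median of -0.18 over 83 members, with rps12 at 0.856 and rplp0 at 1.0, and an interval from redrawn cells of -0.26 to -0.09. Epidermal keratins, which red cells should lack, had a median of 0.84 over 29 members, with krt5 at 2.42 and krt91 at 1.86, beside the larger epidermis-like class of that library.

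The other lists in erythroid-like cells had medians of 0.61 for neutrophil genes (4 members), 0.35 for xenobiotic metabolism, 0.23 for fatty acid and lipoprotein metabolism, 0.21 for stem and progenitor genes, 0.19 for collagens, 0.17 for oxidative stress, 0.13 for lysosome and endocytosis, 0.12 for glycolysis and hypoxia and 0.10 for the circadian clock. In cluster 4 alone the neutrophil median was -0.24 over 3 members. Neuronal genes were at 0.07, nuclear oxidative phosphorylation genes at 0.05, p53 and apoptosis genes at 0.03 and interferon genes at 0.02. Proteasome, mitochondrially encoded and endoplasmic reticulum stress genes were each at -0.03, glucocorticoid response genes at -0.13, muscle genes at -0.31 and crystallins at -0.67. Crystallins are proteins of the lens with few UMIs here, as crybb1 had 60 control and 10 exposed UMIs in cluster 4. Their list was at -1.31 in epidermis-like cells, beside the smaller lens-like class of the exposed library (ratio 0.640). Oxidative stress genes turned to -0.02 with each cell weighted equally, and lysosome genes to -0.04 with all UMIs as the denominator.

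By the rule for named genes, mt2, a metal-binding metallothionein, led the named higher genes of erythroid-like cells at 2.5 (2.31 to 2.70), with UMIs in 246 control and 270 exposed cells. It went both ways elsewhere, at 4.71 in cluster 9, 3.02 in cartilage-like, 10.6 in hair cell or lateral line-like, 0.749 in neural progenitor or glia-like and 0.720 in epidermis-like cells, and 0.939 over all cells outside erythroid-like cells and clusters 9 and 22. The kinase sgk2a at 3.42 (1.85 to 6.60), the lysosomal membrane protein lamp1a at 2.89 (1.64 to 5.24) and NDUFB1 of respiratory complex I at 2.16 (1.60 to 2.93) followed. Then came the heat shock genes hsp70.1 at 1.67 (1.59 to 1.76) and dnajb1b at 1.66 (1.57 to 1.75), rnf150b at 2.79 (1.52 to 5.26) and the heat shock gene hsp90aa1.2 at 1.56 (1.49 to 1.63). Lower were the fatty acid binding protein fabp11a at 0.454 (0.380 to 0.542), the replicative polymerase pole at 0.274 (0.118 to 0.562), the chemokine receptor cxcr4b at 0.424 (0.307 to 0.578), the nucleoside transporter slc29a2 at 0.324 (0.163 to 0.596), exosc7 of the RNA exosome at 0.320 (0.156 to 0.603) and dut. The PCNA partner pclaf was at 0.531 (0.434 to 0.646), the kinetochore gene cenph at 0.318 (0.136 to 0.662) and tsn at 0.318 (0.136 to 0.662). Of 10 places on each side, 2 higher and 1 lower went to loci without a gene name.

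Over all kept cells, lists of blood cells were lower in the exposed library and lists of neurons higher. Heme synthesis genes and erythroid transcription factors each had a median of -0.43, stem and progenitor genes -0.43, G2 and M phase genes -0.65, proteasome genes -0.38 and interferon genes -0.37, while neuronal and synaptic genes were at 0.34 and phototransduction genes at 3.62. Within erythroid-like cells the heme and transcription factor medians were -0.07 and 0.11. Outside those cells and clusters 9 and 22 they were -0.02 and -0.09. The -0.43 of these 2 lists is therefore not read as a lower level within cells, since the shares of erythroid-like and leukocyte-rich cells were lower. Stem and progenitor genes were at 0.21 in erythroid-like cells, 0.15 in cluster 9 and -0.17 outside those cells and clusters 9 and 22. Their -0.43 is thus not read as a lower level within erythroid-like cells or cluster 9. Phototransduction genes had 11 measured members, with rho at 576 control and 12155 exposed UMIs. No cluster was named as photoreceptors, so this list has no value within such a class. Complement and acute phase genes, made mostly in liver, were at 0.65 over 36 members, but at -0.06 with each cell weighted equally. Crystallins, the proteins of the lens, were at -2.03, and at -1.31 in both epidermis-like and fibroblast or mesenchyme-like cells. The list members crybg1b and crybg1a went the other way, at 1.35 and 1.28 over all kept cells and 1.3 and 1.18 in epidermis-like cells. Of the control UMIs, 893 of 1944 for crybg1a lay in epidermis-like cells, beside 156 of 1862 for crybb1. These 2 members are therefore not read as proteins of the lens. Single genes at the extremes came from few cells. The pituitary hormones smtlb (somatolactin) and prl (prolactin) had 3613 and 686 control UMIs against 0 and 6 exposed UMIs, so that the ratio of smtlb had an upper bound of 0.000901. The calcium hormone stc1l had 2557 and 50 UMIs, the pigment enzyme tyrp1b 465 and 4, and the granulin grn2 1213 and 36, while spink2.3 had 1 and 565 and cbln18 10 and 765. Odorant receptors were in both directions, with or111-3 at 0 and 219 UMIs, olfcq1 at 78 and 0, or119-2 at 122 and 2 and or111-6 at 61 and 0; another 7 higher and 2 lower places had no gene name.

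In epidermis-like cells, icn2, a marker of the surface layer, was at 1.79 (1.76 to 1.82), cyp26c1, which breaks down retinoic acid, at 0.396 (0.371 to 0.423) and urgcp at 0.25 (0.140 to 0.430). Of the 3 clusters of this class, cluster 1, which icn2 marks, had the highest ratio of shares at 1.62, beside 1.3 in cluster 3 and 1.29 in cluster 7, and within them icn2 was at 1.24, 1.32 and 1.65. Fibroblast or mesenchyme-like cells had higher fbln1, a matrix protein, at 1.91 (1.73 to 2.12), the fin ray gene and1 at 1.75 (1.69 to 1.82) and hoxb13a at 2.23 (1.68 to 2.97). Cluster 13, which fbln1 marks, held 215 of the control and 254 of the exposed cells of this class, beside 1665 and 1284 in cluster 0, so these values partly reflect the mix of the 2 clusters. Within clusters 13 and 0, fbln1 was at 1.45 (1.3 to 1.61) and 1.61 (1.08 to 2.42), and and1 at 1.29 and 2.02. Their lower genes were the calcitonin gene calca at 0.137 (0.0788 to 0.225), with 50% of its UMIs in 1 cell, and the pancreatic trypsins prss59.1 at 0.179 (0.0939 to 0.318) and prss1 at 0.245 (0.138 to 0.414). Both trypsins were also lower in epidermis-like cells, at 0.361 and 0.402, and prss1 was at 0.558 over all kept cells. The digestive enzyme list went the other way in enterocyte-like cells, with a median log2 ratio of 1.87. The trypsin values are thus not particular to this class, and free RNA was not tested as their source. Across the 12 classes other than erythroid-like cells, 52 places in the ranking had a gene name, and in 43 of them 50% of the UMIs came from at most 5 cells.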

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

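Of the alternatives, those without filters, with top doublet scores removed, or with cells outside the epidermis-like class as the denominator were chosen only after the data were seen. Over all results, 1145 values stayed within their main intervals or within 1.5 times a count, 223 moved and 21 reversed. Where no cause is given, the cause was not tested.

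The erythroid-like share ratio was 0.875 with at least 500 detected genes and 1.04 among blood cells, since leukocyte-rich cells were lower too; it was 0.819 outside the epidermis-like class. The epidermis-like ratio was 1.56 with at least 500 detected genes, 1.32 with no mitochondrial limit, 1.59 at resolution 0.5, 1.33 with each library clustered alone and 1.34 without filters. The cartilage-like ratio reversed to 0.959 with at least 500 detected genes and to 0.726 with each library clustered alone, where the proliferating ratio reversed to 1.49 and 4 of 7 class directions were kept. The fibroblast ratio reversed to 1.26 at resolution 2.0.

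The globin share ratio of erythroid-like cells was 1.0 as a median over cells, 1.04 in cells thinned to 500 UMIs, 1.35 with at least 500 detected genes and 0.831 in cells picked by non-globin markers, which take in many cells with little globin. The cycling share ratio was 0.997 unthinned, where nearly any deep cell has such a UMI, and 0.544 with at least 2 UMIs. With all UMIs as the denominator, the median of all genes in erythroid-like cells was -0.14, since that denominator holds the globins, and the list medians were -0.83 for S phase, -0.05 for transcription factors, -0.10 for membrane genes and -0.04 for lysosome genes. With the mean of per-cell CPM, medians in erythroid-like cells were -0.77 for S phase, 0.14 for larval globins, -0.04 for transcription factors, -0.05 for membrane, -0.03 for mitophagy, -0.02 for heat shock and -0.02 for oxidative stress genes. That scaling gave -0.04 for immediate early and -0.06 for complement genes over all kept cells. With the median of ratios, all kept cells gave 0.01 for oxidative stress, 0.02 for lysosome and 0.02 for collagen genes. In cells thinned to 1000 UMIs, medians were -1.22 for S phase, 0.17 for larval globins, -0.02 for iron handling and -0.03 for membrane genes; larval globins were at 0.44 with at least 500 detected genes. Of the 20 genes in the erythroid-like ranking, 4 stayed with the mean of per-cell CPM, 11 with a minimum of 20 UMIs, 9 with 200 UMIs, 12 with at least 500 detected genes and 5 in thinned cells; a higher minimum and thinning leave fewer genes.

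Adult globins had no measured member and gave no value, and with each library clustered alone 6 of the 7 classes were found. Thinning to 1000 UMIs left out 79 control and 74 exposed erythroid-like cells. At this depth a true ratio of 1.5 gave an interval off 1 for 68.0% of simulated erythroid genes. No paired analysis was possible because each group had 1 library.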

Other observations

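In these observations, the tests on cluster 31 and the S phase list were chosen only after the result was seen, except 1 on low-globin cells inside cluster 4 that was written before its result; the tests on heme synthesis and on near-absent genes were written before theirs, though the near-absent genes themselves had been seen.

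Heme synthesis genes were followed through cells of different globin share, and no difference between these groups of cells was tested. In cluster 4 cells with at least 30% globin (656 control and 500 exposed cells), all 14 measured members were lower in the exposed library, with a median log2 ratio of -0.43 (-0.66 to -0.16 from redrawn cells), urod at 0.511 (0.437 to 0.595), hmbsb at 0.402 (0.273 to 0.580), cpox at 0.422 (0.243 to 0.705), alas2 at 0.814 (0.773 to 0.858) and tspo at 0.996 (0.932 to 1.07). The median was -0.51, -0.44 and -0.28 under the 3 other scalings, with 13 of 14 members lower in the last, and in the same cells keratins (0.69), collagens (0.59), immediate early genes of dissociation (0.37), membrane genes (-0.19), proteasome genes (-0.20) and cytosolic ribosomal proteins (-0.07) also had redrawn intervals off 0. In cluster 4 cells under 30% globin it was -0.01, or -0.49 with each cell weighted equally, and in cluster 31 it was 0.08, while the pooled ratio of all erythroid-like cells was 0.840 (0.666 to 1.03 from redrawn cells) under 30% globin and 0.873 (0.804 to 0.938) at or over it. This was noticed while S phase genes were being examined, and heme synthesis was 1 of 28 lists measured in these cells, so it may be a hypothesis for other libraries and no more. The written test asked whether a different mix of the 2 main erythroid-like clusters shifts the heme list; in cluster 4 as a whole the median was -0.08 (-0.33 to 0.02, or -0.41 to 0.08 from redrawn cells), beside -0.07 over all erythroid-like cells, and the mix cannot be told apart from no difference at this spread.

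Cluster 31, the slc4a1a and urod rich erythroid-like cells, was at 0.739% of control and 0.294% of exposed cells, the lowest ratio of 41 clusters, and the intervals here are widened for that choice. The values argued against the filters set here on detected genes and mitochondrial UMIs. Without either, the share ratio of cluster 31 was 0.376 (0.174 to 0.751). None of the 44 control and 23 exposed erythroid-like cells that returned joined it. With only the mitochondrial limit lifted, 15 and 9 cells joined a wider cluster of 179 and 71, and the ratio was 0.408 (0.253 to 0.641). Cell calling and the removal of dead cells before deposit could not be tested. Doublets stay open, because removing the top doublet scores (0.390) took 0 control and 1 exposed cell from this cluster and doublet calling had not worked. Fewer red cells of every kind would lower cluster 4 as much, and the odds ratio of cluster 31 against it was 0.518 (0.243 to 1.04), while that against the proliferating cluster 22 was 0.553 (0.24 to 1.21), so this and fewer dividing cells of every tissue both stay open. Exposure, a difference in age or parentage between the pools, and uneven recovery of fragile cells may each account for it, and none was tested, as exposure and pool are the same in this design.

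The lower S phase list of erythroid-like cells (-0.67) could come from a different mix of the 2 main erythroid-like clusters, but the median in cluster 4 alone was -0.71 (-1.36 to -0.20) and in cluster 31 -0.35 (-0.80 to 0.09), both from redrawn cells and too wide to decide. Over the cells outside the erythroid-like, leukocyte-rich and proliferating-like cells, the S phase median was -0.39 (-0.42 to -0.36, a counting interval). The interval of red cells (-1.08 to -0.32), from redrawn cells, overlaps it. A like difference in those other cells of the exposed library thus cannot be told apart from one in red cells. Of the cells left out, leukocyte-rich cells were at -0.42 (-0.50 to -0.32, counting). Proliferating-like cells were at -0.09 (-0.22 to 0.06, counting), so the difference was not seen in every class. For fewer low-globin cells inside cluster 4, the test written beforehand gave no median, since only 2 S phase genes had enough UMIs in cells with at least 30% globin. Its replacement for fewer UMIs from low-globin cells weighted the globin bins as in the control library and gave a pooled ratio of 0.745 (0.570 to 0.940, redrawn) beside 0.646 unweighted, and a different mix of cells with 30% to 50% and with over 50% globin was left open by a ratio of 0.709 (0.499 to 1.02, redrawn) in the bin nearer 1. Counting intervals alone would have argued against these explanations, but few cells carried the UMIs, and the exposure itself stays open and untested.

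Over all kept cells, 19 genes were near absent from 1 library, 13 from the control and 6 from the exposed library. A rare cell type caught in 1 library only may explain part of them, and the test left this open. In 5 of the 19 genes the share of cells with a UMI differed within 1 cluster of at least 20 cells per library, which the test counted against it. Those 5 were too few for the bound against it. As 13 of the 19 had such a cluster, the bound for it was not met either. Of the 5, 4 were above the share of cells with a UMI outside that cluster, all in the neutrophil-like sub-cluster, where spink2.3 was in 11 of 34 exposed and 0 of 51 control cells, while stc1l, in 4.57% of control cells of cluster 2 (3.27 to 6.20) and 3.30% outside it (2.96 to 3.66), was not, which free RNA would give as well. For cbln18, 97.0% of the UMIs lay in cluster 36, which had 12 control and 47 exposed cells. For smtlb, prl, tyrp1b, grn2 and also stc1l, 50% of the UMIs came from 1 cell each. Sequence differences between the pools and the exposure were not tested.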
